A study of Homo sapiens with 6 samples.

How the data were processed

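Total RNA from SCC1 cells was purified with a NucleoSpin kit and made into KAPA RNA-Seq libraries, per the labels' protocols; neither strand handling nor the read layout is stated there. The 5 deposited tables give for each gene symbol the level in an untreated and a treated library, a fold change, a p-value and an FDR. The submitters' processing notes name TopHat, Cufflinks and the build hg18, without versions. The counter, the scaling and the test are not given in the sources used here, and no coordinates are printed, because the reference supplied is of another build and served for gene names only. The deposited signal columns hold read counts multiplied by 1 factor per library: 100% of values were whole multiples of the value of 1 read within a tolerance of 0.01. They are therefore normalized counts on the CPM scale, with column totals between 924229 and 1107155. The deposited fold change is a signed score, minus the inverse ratio where lower, and the deposited p-value compares 1 library with 1 library, so it speaks of those libraries, not of the conditions. Each deposited file held 23 entries whose symbol had become a calendar date, and these were left out.

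The JQ1 and I-BET tables share an untreated column over 16067 symbols (table set 1), and the INF-r and combination tables share another over 15116 (table set 2). Their headers match the 1 untreated sample of the labels, but the columns hold different reads (chi-square per degree of freedom 9.40 over 12426 genes with 20 or more reads), so they were kept apart as set-specific columns. 14761 symbols stand in both sets. The depth was 4559420 to 13668082 reads, deeper in table set 1, and 1 read was worth 0.0731 to 0.211 CPM. A count of 0 allows up to 3 reads, 0.219 to 0.632 CPM. Ratios carry an exact 95% binomial (Clopper-Pearson) interval conditional on the summed reads, for counting error only, since reads without molecular identifiers are not independent molecules. The 10 most abundant genes took 4.37% and 4.38% of reads in the untreated columns and 7.26% to 8.22% with the inhibitors alone.

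Conditions, comparisons and gene lists were fixed before the data were examined. Of the alternatives, the pseudocount, level filter, median-centring and authors' calls were planned, except for the correlations. The others were chosen after the data were seen. The plan expected FPKM and stated that CPM would take its place, still with no test, if counts were found. For each of 9 comparisons a gene was counted as higher or lower at a log2((CPM + 1)/(CPM + 1)) of at least 1 or at most -1, among genes at 1 CPM or more in either library; this scale understates the change of low genes. Each of 26 gene lists was described by its median and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins, and stands apart at percentile 98 or more or 2 or less. The genes named are, per comparison, at most 4 examples per list past 2-fold and at 5 CPM or more, the 5 largest differences each way at 5 CPM or more, and 12 fixed genes, some of which are not reported here; symbols are those of the files (WARS, CTGF, CYR61 and HIST names are older symbols). Where a gene named for 1 comparison is given in another, its level completes the series. Genes with near-identical copies, readthrough genes and antisense genes are uncertain, since the files do not say how shared reads were counted.

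After the data were seen, the recovered reads of the 7 libraries, which are 6 samples with the untreated sample entered once per table set, were fitted with edgeR 4.0.16 (quasi-likelihood test, TMM, R 4.3.3) on genes at 1 CPM or more in 2 libraries, with table set, inhibitor and INF-r as terms, and with a compound term or an interaction in further fits. Adjusted p-values are Benjamini-Hochberg values over all genes tested, at a threshold of 0.05. Nothing says that the libraries came from separate cultures, so these p-values measure the spread between libraries, which includes real differences between compounds and between backgrounds. In the interaction fit the untreated columns and the INF-r library are fitted exactly and add no spread. Its p-values measure the spread between JQ1 and I-BET in each table set. DESeq2 1.42.0, RLE normalization, no filter and leaving out each library were alternatives, and so was the untreated column of the other table set for the single comparisons. Both procedures were tested on simulated data with 200 changed genes: the size rule recovered 200 of the 200 4-fold changes simulated with counting noise from the untreated library of table set 1 over 12628 genes. Those changed genes were drawn only from well-expressed genes of that library, the deepest. The result therefore does not speak of low genes or of the depth of table set 2. The model recovered 78% of inhibitor changes at a log2 of 1 and 96% at 2 over 12999 genes, and for INF-r 35% and 87% over 13004 genes. That simulation gave every gene the same dispersion and held no compound difference and no interaction. Its recovery therefore need not hold for the real libraries. Shared controls were simulated 100 times at the model's common dispersion of 0.0207. The remaining steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.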

Results

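RNA was sequenced from SCC1 cells, a line of head and neck squamous cell carcinoma, after overnight culture under 6 conditions, with 1 sample each. The cells were left untreated or received 500 nM JQ1, 500 nM I-BET, 10 ng/ml INF-r, JQ1 with INF-r, or I-BET with INF-r. JQ1 is an inhibitor of the BET bromodomain proteins that bind acetylated histones; the labels do not say which I-BET compound was used. The agent that the labels call INF-r is written IFN in the file headers. The deposited tables fell into 2 sets that were scaled separately. Table set 1 held the untreated, JQ1 and I-BET libraries with 13668082, 12161065 and 12977990 recovered reads. Table set 2 held an untreated column, INF-r, JQ1 with INF-r and I-BET with INF-r, with 4559420, 4663450, 5462017 and 4603512 reads. Both untreated columns are mapped to the 1 untreated sample of the labels, although their reads differ, so every comparison was made inside its own table set. Levels are normalized read counts on the CPM scale, and differences are log2 ratios after adding 1 CPM. With 1 library per condition no difference between conditions has a replicate check, and the intervals given are counting error only. As a scale, the untreated columns of the 2 sets themselves differed at least 2-fold at 3.47% of 12840 genes, with 226 higher and 219 lower in table set 2. Among the named genes this held for ANKRD1, CDKN1A, CHAC1, CSF3, CTSS, FOS, GTF2H2C, LIF, MMP3, NOMO3, PDCD1LG2, SERPINI1, SMN1, SMN2, SOCS1 and TGFB2.

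**Figure D1:**
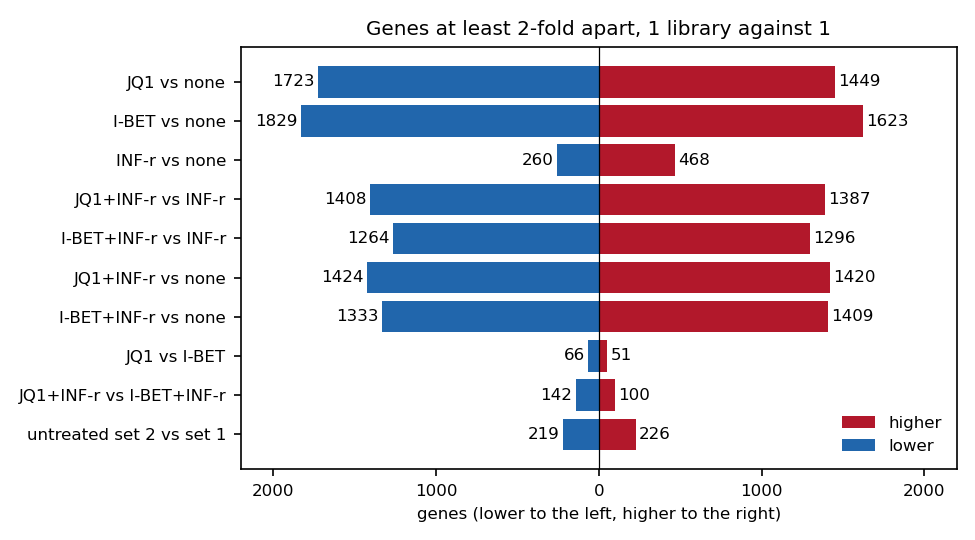
Number of genes at least 2-fold higher (right) or lower (left) on the log2(CPM + 1) scale in each comparison of 1 library with 1 library, among genes at 1 CPM or more in either. The inhibitor comparisons gave 1723 and 1829 lower genes without INF-r, INF-r alone gave 468 higher genes, and the bottom bar sets the untreated column of table set 2 against that of table set 1.

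The effect of each BET inhibitor alone was read from table set 1. HEXIM1, which holds the elongation factor P-TEFb inactive and is widely used as a marker of BET inhibition, stood at 140.3, 1002 and 1063 CPM without treatment, with JQ1 and with I-BET. That was higher by 7.14-fold (95% counting interval 6.80 to 7.50) with JQ1 and by 7.57-fold (95% counting interval 7.22 to 7.95) with I-BET. SERPINI1 was at 3.58, 59.3 and 64.8 CPM in the same order, and BRD2, itself a BET protein, at 364, 1474 and 1638 CPM, whereas ZMYND8 was lower at 54, 18.9 and 17.2 CPM. The list of BET proteins and P-TEFb as a whole did not stand apart (median log2 difference 0.03, percentile 56.4 with JQ1; 0.01, percentile 53.6 with I-BET). Histone genes were higher in 14 of 17 members with JQ1 and 15 of 17 with I-BET, with medians of 2.66 and 2.79. HIST2H2BE went from 3.66 to 173 and 202 CPM and HIST1H2BD from 10.2 to 281 and 277 CPM; near-identical histone copies can share reads. Outside the lists, EFR3B (0.293, 57.4 and 80.1 CPM), the creatine transporter SLC6A8 (19.1, 716 and 767 CPM) and PEG10 (91.3, 2400.2 and 2657 CPM) were among the 5 most raised genes with either compound.

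Genes of DNA replication and division were lower as a group with either inhibitor. In the list of S phase and mitosis, 30 of 40 genes were lower with JQ1 and 34 of 40 with I-BET, and none was higher, with medians of -1.56 and -1.82 (percentiles 0 and 0 among random lists). The replication helicase subunit MCM5 went from 321 to 17.2 and 15 CPM, the origin licensing factor CDT1 was at 110.5, 7.43 and 5.03 CPM, and UHRF1, needed to maintain DNA methylation, at 384, 31.1 and 28.7 CPM. CDKN1A, which encodes the CDK inhibitor p21, was higher by 16.6-fold (95% counting interval 15.3 to 18) and 19.4-fold (95% counting interval 17.9 to 21.1). The list of CDK inhibitors and p53 targets was higher in 12 of 21 and 11 of 21 members and lower in 1 and 1, among them TP53INP1 (2.71, 46.2 and 40.9 CPM) and GADD45B (19.6, 141 and 191 CPM). MYC, the growth-driving transcription factor, was at 159, 83.9 and 95.5 CPM, a difference of -0.92 and -0.73 that did not reach 2-fold. Its list had medians of -0.53, percentile 0.0200 and -0.66, percentile 0, with 4 of 26 and 7 of 26 lower and 2 and 3 higher; RRS1, a ribosome assembly factor, was at 178, 45 and 41.7 CPM and CDK4 at 132, 55.8 and 46.2 CPM, where JQ1 was under 2-fold against the other untreated column (-0.94). MYCL went the other way, at 1.83, 13.5 and 11.2 CPM. Of the apoptosis regulators 3 of 18 and 4 of 18 were higher and 3 and 3 lower (medians -0.20, percentile 19.3 and -0.37, percentile 5.76). BCL2L11, which encodes the pro-apoptotic BIM, was at 21.2, 87.8 and 129 CPM and BCL2 at 5.19, 0.906 and 0.682 CPM.

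IL1B, an inflammatory cytokine gene, was among the 5 most reduced genes with either compound, lower by 66.2-fold (95% counting interval 41.2 to 114) with JQ1 and 74.7-fold (95% counting interval 45.9 to 131) with I-BET, and IL1A was at 461, 22.6 and 9.04 CPM. CSF3, encoding the granulocyte growth factor G-CSF, was at 47.5, 3.72 and 1.96 CPM, but against the untreated column of table set 2, at 6.49 CPM, the JQ1 difference was -0.67. LIF was at 132, 20.5 and 8.28 CPM. The list of NF-kB cytokines and feedback genes was lower in 13 of 20 and 14 of 20 members and higher in 2 and 1 (medians -1.52, percentile 0 and -1.77, percentile 0). The interleukin 7 receptor gene IL7R, in no list, was at 86.8, 0.725 and 0.768 CPM and the activin antagonist FST at 74.1, 2.27 and 2.22 CPM. Genes of classical MHC class I, which present peptides to cytotoxic T cells, were higher: HLA-B at 200.4, 304 and 315 CPM, HLA-C at 248, 443 and 453 CPM and B2M, their shared light chain, at 440.4, 929 and 893 CPM. Among these 3, B2M alone passed 2-fold (1.08 and 1.02); against the other untreated column HLA-C did so too (1.12 and 1.16). The HLA genes are close paralogs whose reads may be shared. HLA-E was at 166, 461 and 447 CPM. The immunoproteasome gene PSMB8 (53.5, 23.3 and 18.3 CPM) and the peptide trimming gene ERAP2 (111, 38.3 and 34.8 CPM) were lower, and the peptide transporter gene TAP1 was at 93.9, 80.2 and 63.5 CPM, so the list median was near 0 (0.17, percentile 79.1 and -0.02, percentile 40.7). MHC class II genes were scarcely detected, with 4 and 5 past the level filter and medians of 1.04, percentile 98.2 and 0.98, percentile 96.3. IFI30 was at 28.6, 88.7 and 77.5 CPM, and CIITA, the class II activator, and CXCL10 had 0 reads in the 3 libraries of this set, which allows up to 0.219 CPM in the untreated library. Guanylate-binding and other interferon-gamma genes were lower in 11 of 28 and 12 of 28 members and higher in 3 and 4 (medians -0.21, percentile 15.3 and -0.49, percentile 1.04), with GBP1 at 31.1, 4.08 and 3.41 CPM and APOL6 at 38.6, 6.07 and 2.56 CPM. Antiviral genes were lower in 5 of 25 and 9 of 25 members and higher in 3 and 3 (medians -0.61, percentile 0.790 and -0.70, percentile 0.290); OAS3 was at 185, 41.2 and 37 CPM, whereas IRF7 was higher at 19.4, 156 and 151 CPM. IRF1 (0.08 and -0.17) was less than 2-fold from the untreated library. CD274, which encodes PD-L1, was at 8.92, 3.99 and 5.29 CPM, and the list of immune checkpoint ligands had medians of -0.46, percentile 8.44 and -0.46, percentile 9.08. CXCL16, the T cell chemokine gene past the level filter, was at 27.2, 11.7 and 8.62 CPM.

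The squamous lineage genes split. TP63, the basal keratinocyte transcription factor, was lower at 216, 24.5 and 16.1 CPM, while KRT16 (2.05, 27 and 23.2 CPM) and NOTCH1 (46.4, 164 and 137 CPM) were higher, NOTCH1 by just under 2-fold with JQ1 and by 0.74 with I-BET against the other untreated column, and the list of squamous basal identity had medians of -0.19, percentile 9.24 and -0.25, percentile 5.30. Among epidermal differentiation genes the cornified envelope gene PPL was at 118, 505 and 604 CPM and KRT80 at 38.9, 8.16 and 4.35 CPM (list medians -0.19, percentile 28.8 and 0.12, percentile 60.2). In the list of mesenchymal and invasion genes the matrix protease gene MMP3 was at 424, 44.4 and 48.1 CPM and PDPN at 27.4, 2.99 and 4.27 CPM, whereas SERPINE2 was at 1.39, 16.4 and 18.7 CPM (medians -0.64, percentile 0 and -0.29, percentile 3.03). Immediate early genes were higher in 8 of 22 and 12 of 22 members and lower in none, with ATF3 at 8.63, 81.4 and 79.3 CPM and FOS at 1.24, 15.1 and 21.2 CPM. Among TGF-beta and YAP targets CTGF was at 89.9, 1252 and 2579 CPM and TGFB1 at 95, 408 and 524 CPM, and the list medians were -0.15, percentile 17.2 and 0.00, percentile 47.9. Of the markers of stem-like tumour cells, BMI1, a Polycomb repressor, was at 48.4, 6.44 and 4.27 CPM and ABCG2 at 25.4, 4.26 and 3.16 CPM (medians -0.88, percentile 1.38 and -1.23, percentile 0.240). Sterol synthesis genes were higher in 9 of 19 and 8 of 19 members and lower in 1 and 1, with INSIG1 at 22.2, 203 and 159 CPM, and glycolysis and hypoxia genes in 9 of 21 and 7 of 21, with NDRG1 at 17.8, 151 and 186 CPM. The latter list no longer stood apart at a level filter of 5 CPM (medians 0.24 and 0.37). The unfolded protein and integrated stress response list was higher in 10 of 17 members with JQ1 and 4 of 17 with I-BET and lower in 0 and 2, led by ASNS, the asparagine synthetase gene (56.2, 929 and 284 CPM). The housekeeping list had medians of 0.14, percentile 63.4 and 0.16, percentile 72.6, but its members POLR2A (334, 1545 and 1575 CPM) and GAPDH (4142, 8454 and 8449 CPM) were higher and TUBB (1876, 567 and 568 CPM) lower. The directions of these 3 were the same after centring on the median gene.

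In all, 1449 genes were higher and 1723 lower with JQ1 among 13009, and 1623 higher and 1829 lower with I-BET among 13109. In the authors' deposited table an FDR under 0.05 was given to 450 higher and 539 lower genes for JQ1 and to 618 and 678 for I-BET. To set the inhibitor effect against a spread between libraries, a count model (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, 3 residual degrees of freedom) was fitted to the recovered reads of the 7 libraries with table set, inhibitor and INF-r as terms. Both untreated columns entered as libraries of their own, although they carry the label of 1 untreated sample. That of table set 2 is the 1 library there without INF-r, so it is fitted exactly and does not enter the inhibitor term. The controls of that term are the untreated column of table set 1 and the INF-r library. It treats JQ1 and I-BET as examples of 1 class, so its spread is that between compounds and settings, not between replicate cultures. Of 13220 genes tested, 3297 rose and 3637 fell with an inhibitor. Without the untreated column of table set 1, 2395 and 2657 did so. Leaving out that of table set 2 gave 3304 and 3602, which is no check. It can act on this term only through the gene filter, the scaling and the shared dispersion. HEXIM1 rose by a log2 change of 2.46 ± 0.21 (SE, adjusted p = 1.46e-04), B2M by 0.84 ± 0.12 (SE, adjusted p = 8.98e-04) and HLA-C by 0.76 ± 0.09 (SE, adjusted p = 5.53e-04). MYC had a change of -0.99 ± 0.11 (SE, adjusted p = 3.34e-04), TP63 of -2.49 ± 0.41 (SE, adjusted p = 0.00188) and IL1B of -5.98 ± 0.16 (SE, adjusted p = 7.89e-06). Each of these 6 genes went the same way in the 4 comparisons of an inhibitor with its control library. In the list of MHC class I and peptide loading, to which B2M and HLA-C belong, 6 rose and 5 fell of 21 tested, and 6 and 5 when adjusted over the list alone (median change 0.13). For the interferon-gamma list 4 rose and 15 fell of 31 tested, and 4 and 15 when adjusted over the list alone, and for the antiviral list 4 rose and 15 fell of 33 tested, and 5 and 16 when adjusted over the list alone. In the list of S phase and mitosis 0 rose and 37 fell of 40 tested, and 0 and 38 when adjusted over the list alone. In that of histone genes 15 rose and 0 fell of 17 tested, and 15 and 0 when adjusted over the list alone. In that of NF-kB cytokines and feedback genes 0 rose and 14 fell of 20 tested, and 0 and 15 when adjusted over the list alone. For MYC and its targets 3 rose and 17 fell of 26 tested, and 3 and 17 when adjusted over the list alone. For the sterol synthesis genes 12 rose and 1 fell of 19 tested, and 12 and 1 when adjusted over the list alone, and for the CDK inhibitors and p53 targets 13 rose and 2 fell of 21 tested, and 14 and 2 when adjusted over the list alone. The stress response list, higher by size, went both ways here: 4 rose and 4 fell of 17 tested, and 4 and 4 when adjusted over the list alone. For immediate early genes, none of which was lower by size without INF-r, 7 rose and 2 fell of 22 tested, and 7 and 2 when adjusted over the list alone. Given in the same way, with list-alone counts in brackets, the counts were 2 and 2 of 7 (2 and 3) for class II, 0 and 7 of 10 (0 and 7) for checkpoint ligands, 9 and 5 of 19 (9 and 6) for BET proteins and P-TEFb and 5 and 9 of 19 (5 and 9) for apoptosis regulators. They were 5 and 9 of 22 (6 and 9) for squamous basal identity, 5 and 4 of 15 (5 and 4) for epidermal differentiation, 3 and 8 of 28 (3 and 8) for mesenchymal genes, 5 and 7 of 20 (5 and 7) for TGF-beta and YAP targets, 0 and 4 of 7 (0 and 4) for stem-like markers, 8 and 3 of 21 (8 and 3) for glycolysis and hypoxia and 4 and 3 of 16 (4 and 3) for housekeeping genes.

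INF-r alone was read in table set 2 against that set's untreated column. Antigen presentation and interferon-stimulated genes were higher together. HLA-B went from 173 to 1259 CPM, HLA-C from 203 to 794 CPM and B2M from 433 to 2001 CPM. TAP1 was higher by 14.4-fold (95% counting interval 13.1 to 15.8), and the immunoproteasome gene PSMB10 and the class I activator gene NLRC5 went from 11.6 to 227 and from 18.9 to 201 CPM. In the list of MHC class I and peptide loading 18 of 21 genes were higher and none lower (median 2.21, percentile 100). CIITA had 0 reads without INF-r and 18.5 CPM with it, at least 30.5-fold higher against the limit of 3 reads, and the class II chaperone gene CD74 went from 0.203 to 48.3 CPM; 6 of 7 class II genes were higher. IRF1, an interferon-induced transcription factor gene, was higher by 33.5-fold (95% counting interval 28.3 to 39.9), and GBP1 and GBP4 went from 23.7 to 1399 and from 1.22 to 885 CPM. IDO1, the tryptophan-degrading enzyme gene, had 0 reads without INF-r and was at least 328-fold higher. Of the interferon-gamma list 27 of 31 and of the antiviral list 34 of 35 were higher, with OAS2 from 0.811 to 106 CPM and IFITM1 from 2.84 to 182 CPM (medians 3.32 and 2.25). CXCL10, a chemokine that draws T cells, had 3 reads without and 1173 with INF-r, a ratio of 402 (95% counting interval 137 to 1949.9), and CXCL11 went from 0.405 to 111 CPM; 3 of 4 T cell-attracting chemokine genes past the level filter were higher. CD274 went from 6.49 to 52.9 CPM and PDCD1LG2, which encodes PD-L2, from 0.811 to 25.2 CPM, with 6 of 11 checkpoint ligand genes higher (median 1.30, percentile 100).

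MYC and HEXIM1 were within 2-fold with INF-r alone: MYC was at 129 and 137 CPM and HEXIM1 at 117 and 115 CPM. None of 40 S phase and mitosis genes passed 2-fold, although their small median (-0.06, percentile 0.510) was low among random lists, and the medians were 0.01 for MYC and its targets, 0.02 for BET proteins and P-TEFb and 0.02 for histone genes. Sterol synthesis (-0.23, percentile 0), the stress response list (-0.22, percentile 0.0400) and TGF-beta and YAP targets (-0.18, percentile 0.110) had low medians with 0, 0 and 2 genes past 2-fold; TGFB2 went from 15.4 to 2.29 CPM. At a level filter of 5 CPM the TGF-beta and YAP list no longer stood apart (median -0.08). Higher medians were found for NF-kB genes (0.26, percentile 99.99), apoptosis regulators (0.39, percentile 100) and immediate early genes (0.43, percentile 100). By 2-fold, 4 of 19 NF-kB genes and 3 of 17 apoptosis regulators were higher, and 0 immediate early genes were higher and 1 lower of 21, with SOD2 from 127 to 709.7 CPM and TNFSF10, the gene of the death ligand TRAIL, from 5.68 to 39.1 CPM. Of those 4 NF-kB genes, CXCL2 (0.52) and NFKBIZ (0.84) fell under 2-fold against the other untreated column, and CSF3 changed direction (-1.44). KLF4 went from 14.8 to 98.7 CPM and KRT80 from 42.4 to 8.33 CPM in the differentiation list (-0.22, percentile 6.97), and KRT17 from 218 to 516 CPM in the basal list (0.03, percentile 68.4). The medians of CDK inhibitors and p53 targets (-0.11, percentile 20.1), mesenchymal genes (-0.06, percentile 10), stem-like markers (-0.04, percentile 39), glycolysis and hypoxia (0.09, percentile 95.7) and housekeeping genes (0.04, percentile 64.4) did not stand apart.

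With INF-r alone, 468 genes were higher and 260 lower among 12996. A level filter of 5 CPM left 307 and 127, a pseudocount of 0.1 gave 587 lower genes, and the authors' deposited table called 126 higher and 12 lower at an FDR under 0.05. The 5 genes furthest down, led by NOMO3 (27 to 0.208 CPM) and GTF2H2C (12 to 0 CPM), are near-identical copies or readthrough genes whose reads can be assigned elsewhere, so they are uncertain. In the additive model 112 genes rose and 3 fell with INF-r (edgeR, adjusted p under 0.05; 1074 genes had an unadjusted p under 0.05, and DESeq2 gave 193 and 16). HLA-B rose by 2.82 ± 0.16 (SE, adjusted p = 5.87e-04), IRF1 by 5.12 ± 0.26 (SE, adjusted p = 3.64e-04), TAP1 by 4.17 ± 0.43 (SE, adjusted p = 0.00618) and CD274 by 2.92 ± 0.32 (SE, adjusted p = 0.00929). These 4 genes were higher with INF-r without inhibitor, with JQ1 and with I-BET, in differences that all use the untreated column of table set 2. For MHC class I and peptide loading 17 rose and 0 fell of 21 tested, and 18 and 0 when adjusted over the list alone. For class II 2 rose and 0 fell of 7 tested (4 and 0 over the list alone), and for checkpoint ligands 3 and 0 of 10 (5 and 0). For T cell-attracting chemokines 1 rose and 0 fell of 2 tested (2 and 0 over the list alone, DESeq2 0 and 0). For the interferon-gamma list 19 rose and 0 fell of 31 tested, and 27 and 0 when adjusted over the list alone, and for the antiviral list 19 rose and 0 fell of 33 tested, and 28 and 0 when adjusted over the list alone. For the NF-kB list 0 rose and 0 fell of 20 tested, and 0 and 0 when adjusted over the list alone (unadjusted p under 0.05 at 4 and 1, DESeq2 0 and 0). For immediate early genes 0 rose and 0 fell of 22 tested, and 0 and 1 when adjusted over the list alone (median change -0.01, unadjusted 1 and 1, DESeq2 0 and 1), and for apoptosis regulators 1 rose and 0 fell of 19 tested, and 5 and 0 when adjusted over the list alone. The reference for this term was the 1 untreated column of table set 2, so INF-r and table set could not be separated without it. The counts with INF-r were 491 and 225 without the INF-r library, 298 and 60 without the untreated column of table set 1, and 44 and 1 without JQ1 with INF-r.

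**Figure D2:**
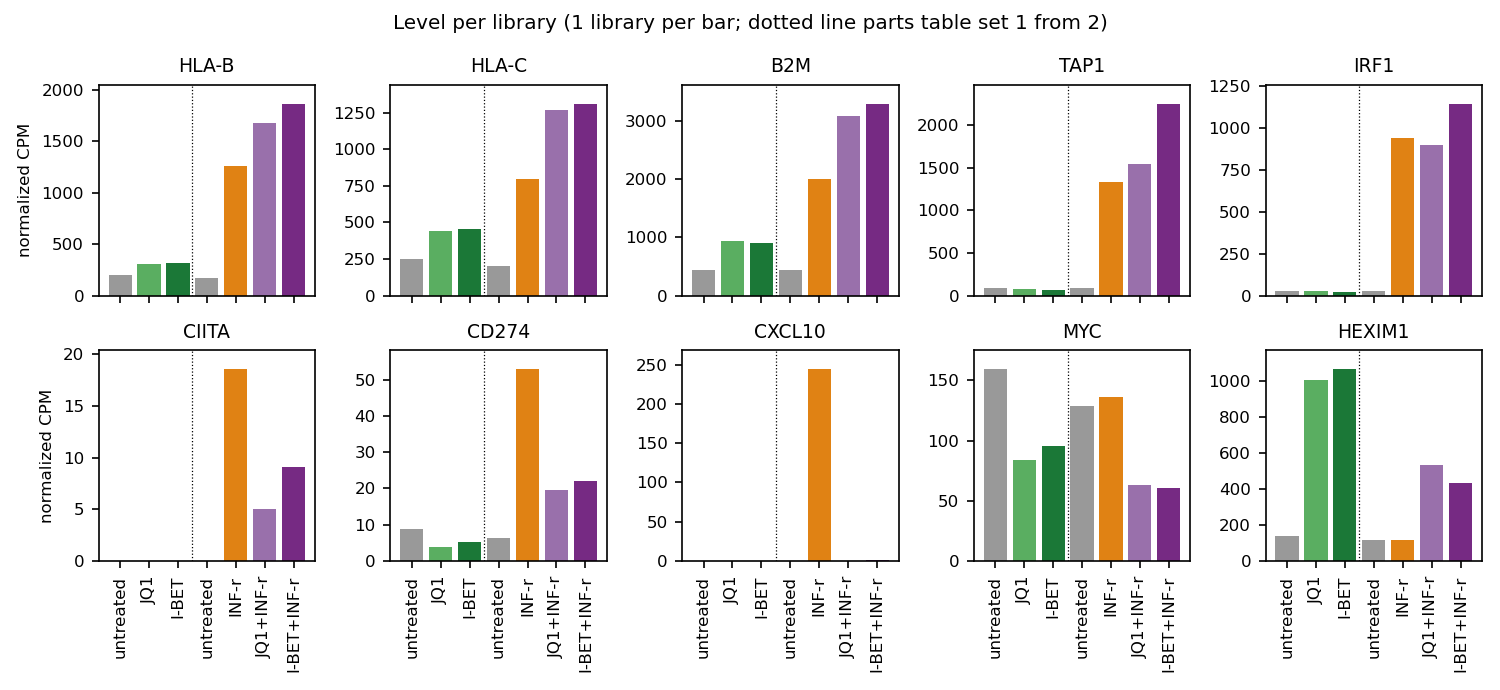
Level in normalized CPM of 10 genes fixed in advance, 1 bar per library, each panel with its own axis from 0; the dotted line parts table set 1 from table set 2, which were scaled separately. HLA-B stands at 1259 CPM with INF-r and at 1675 and 1864 with an inhibitor added, while CXCL10 stands at 244 and then at 0.541 and 1.69 CPM.

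Adding an inhibitor to INF-r was compared with INF-r alone, and levels are given for INF-r, JQ1 with INF-r and I-BET with INF-r in that order. Of the genes higher with INF-r, some were lower with an inhibitor added and some higher. CXCL10 was at 244, 0.541 and 1.69 CPM, lower by 145-fold (95% counting interval 73.3 to 336) with I-BET and by 451-fold (95% counting interval 154 to 2191) with JQ1, where 3 reads were left. CXCL11 was at 111, 0.361 and 0.421 CPM, and CXCL9 had 0 reads with either inhibitor, at least 24.2-fold and 20.8-fold lower. Of the T cell-attracting chemokine genes 3 of 4 and 3 of 4 past the level filter were lower. IDO1 was at 199, 5.05 and 7.58 CPM, GBP1 at 1399, 175 and 229 CPM, GBP5 at 36.6, 1.44 and 1.47 CPM and the antiviral membrane protein gene IFITM1 at 182, 8.30 and 11.8 CPM. The class II genes CD74 (48.3, 6.31 and 11 CPM) and CTSS (59.1, 1.62 and 3.16 CPM) were lower, and CIITA was at 18.5, 5.05 and 9.06 CPM. CD274 was at 52.9, 19.5 and 22.1 CPM, a difference of -1.40 and -1.22, and PDCD1LG2 at 25.2, 3.43 and 7.80 CPM, with 6 of 11 and 6 of 11 checkpoint ligand genes lower (medians -1.26, percentile 0 and -1.06, percentile 0). HLA-E was at 637, 1366 and 1386 CPM, HLA-B at 1259, 1675 and 1864 CPM, HLA-C at 794, 1269 and 1311 CPM, B2M at 2001, 3077 and 3294 CPM and TAP1 at 1339, 1550.5 and 2256 CPM; of these HLA-E passed 2-fold. No gene of the class I list was lower by 2-fold in either comparison (medians 0.13, percentile 90.7 and 0.32, percentile 99.9). IRF1 was at 943, 898 and 1145 CPM. APOL1 was at 273, 955 and 1029.8 CPM and ISG15 at 46.2, 155 and 148 CPM. In the interferon-gamma list 13 and 9 of 31 genes were lower and 4 and 3 higher (medians -0.91, percentile 0 and -0.55, percentile 0), and in the antiviral list 13 and 12 of 35 lower and 4 and 5 higher (medians -0.68, percentile 0 and -0.38, percentile 0.240). The class II list had medians of -0.66, percentile 3.62 and 0.34, percentile 75; at a level filter of 5 CPM these were -2.22 and -0.96 and both stood apart.

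**Figure D3:**
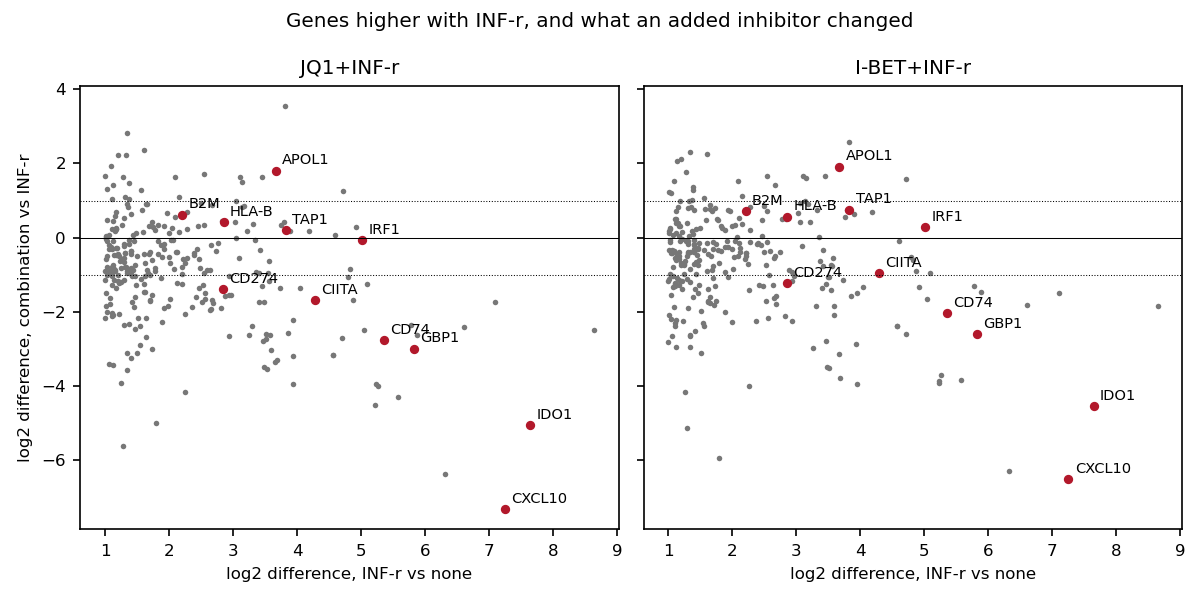
Each point is 1 of the 305 genes in both table sets that were at least 2-fold higher with INF-r and at 5 CPM or more there; the x axis is the log2 difference of INF-r against untreated, the y axis that of JQ1 with INF-r (left) or I-BET with INF-r (right) against INF-r, and dotted lines mark 2-fold. APOL1 lies at 1.80 and 1.91 and GBP1 at -2.99 and -2.60; both axes use the INF-r library, so chance there tilts the cloud downward.

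Histone, S phase and NF-kB genes differed from INF-r alone in the direction they had without INF-r. HEXIM1 was at 115, 530.1 and 432 CPM, SERPINI1 at 1.25, 20 and 22.1 CPM and MYC at 137, 63.1 and 60.7 CPM. Histone genes were higher in 12 of 15 and 12 of 15 members, S phase and mitosis genes lower in 33 of 40 and 35 of 40 and NF-kB genes lower in 12 of 19 and 12 of 19, with MCM5 at 265, 33.9 and 38.8 CPM, IL1A at 333, 12.6 and 8.64 CPM and IL1B at 94.5, 1.44 and 2.11 CPM. MMP3 was at 161, 2.35 and 2.11 CPM, TNC, a matrix glycoprotein gene, at 414, 63.9 and 68.7 CPM and the AP-1 subunit gene FOSL1 at 250.2, 48.7 and 46.1 CPM. TP63 was at 211, 87.1 and 79.2 CPM and CDKN1A at 33.9, 163 and 152 CPM. The medians were 0.90, percentile 100 and 0.91, percentile 100 for CDK inhibitors and p53 targets, 0.77, percentile 100 and 0.60, percentile 100 for sterol synthesis, -0.64, percentile 0 and -0.71, percentile 0 for MYC and its targets, -0.38, percentile 1.38 and -0.34, percentile 2.41 for squamous basal identity, and -0.41, percentile 1.94 and -0.37, percentile 2.68 for apoptosis regulators. Immediate early genes, higher without INF-r, had medians of -0.20, percentile 14.5 and -0.15, percentile 22.3, and the stress response list -0.03, percentile 50.6 and -0.05, percentile 47.9. SMN2 (70.4, 0 and 55 CPM) was among the 5 lowest genes with JQ1, but its near-identical copy SMN1 can take its reads. In all, 1387 genes were higher and 1408 lower with JQ1 among 13181, and 1296 and 1264 with I-BET among 13216. Neither comparison is in the authors' deposited tables used here.

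Each combination was then compared with untreated cells. HLA-B was at 173 CPM untreated, 1675 with JQ1 and INF-r and 1864 with I-BET and INF-r, a difference of 3.27 and 3.42, and TAP1 differed by 4.04 and 4.58. The tryptophanyl-tRNA synthetase gene WARS was at 175, 11113 and 13757 CPM. CD274 remained above the untreated level by 1.45 and 1.63. CXCL10 had 3 reads untreated, 3 with JQ1 and INF-r and 8 with I-BET and INF-r, a ratio of 2.77 (95% counting interval 0.665 to 16.2) for the latter. MYC differed by -1.02 and -1.07 and HEXIM1 by 2.17 and 1.87. The class I list was higher in 17 of 21 and 17 of 21 genes, the interferon-gamma list in 24 of 31 and 26 of 31 (lower in 1 and 1), and the antiviral list in 27 of 32 and 30 of 33. S phase and mitosis genes were lower in 34 of 40 and 37 of 40. The checkpoint ligand list had medians of 0.67, percentile 99 and 0.71, percentile 99.4, which did not stand apart at a level filter of 5 CPM (0.26 and 0.60). JQ1 with INF-r gave 1420 higher and 1424 lower genes and I-BET with INF-r 1409 and 1333, where the authors' deposited table called 276 and 205, and 274 and 163, at an FDR under 0.05.

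The INF-r effect was then set side by side in 3 backgrounds, without inhibitor, with JQ1 and with I-BET, each condition taken relative to the untreated column of its own table set. With an inhibitor it is the difference of the combination minus that of the inhibitor alone. For HLA-B the log2 differences were 2.85, 2.67 and 2.77, for B2M 2.21, 1.75 and 1.91, for TAP1 3.83, 4.27 and 5.14 and for IRF1 5.02, 4.87 and 5.47. For APOL1 they were 3.67, 5.59 and 6.11 and for WARS 4.72, 5.93 and 6.47. For CD274 they were 2.85, 2.44 and 2.28, for GBP1 5.82, 5.49 and 6.08 and for IFITM1 5.57, 2.88 and 3.37. The T cell-attracting chemokine genes differed in this, with 7.25, -0.06 and 0.74 for CXCL10 and 6.32, -0.17 and -0.10 for CXCL11, which had few reads outside the INF-r library, and 0.83, 1.30 and 1.88 for CXCL16. Of 455 genes at least 2-fold higher with INF-r and no inhibitor, 204 were so in the 3 backgrounds and 169 were under 2-fold both with JQ1 and with I-BET. In the other direction, 37 genes were lower in the 3 backgrounds. The 3 differences all use the untreated column of table set 2, and those with an inhibitor also share that of table set 1. Chance in a shared column moves them together, so the 3 backgrounds are not independent checks. At a pseudocount of 0.1, 386 were higher and 167 lower in the 3 backgrounds, and at a level filter of 5 CPM 20 were lower. The median change of the INF-r effect was -0.04 with JQ1 and 0.39 with I-BET for the class I list, -1.16 and -0.92 for class II, -0.19 and 0.26 for the interferon-gamma list, -0.17 and 0.10 for antiviral genes, and -0.94 and -1.33 for immediate early genes. The class II value with JQ1 was -2.05 at a pseudocount of 0.1 and -1.69 at a level filter of 5 CPM. For the unfolded protein and integrated stress response the changes were -1.17 and -0.35. A count model with an interaction term (edgeR, 2 residual degrees of freedom) called 362 genes with a more positive and 238 with a more negative inhibitor effect with INF-r than without, where DESeq2 gave 140 and 160. Libraries with INF-r stand in table set 2 alone, so the interaction cannot be told apart from other differences between the sets, in counting, preparation or culture. The untreated columns and the INF-r library are fitted exactly here, so the p-values measure the spread between JQ1 and I-BET. The untreated column of table set 2 does not enter the interaction, so the 357 and 236 genes called without it are no check. The term could not be fitted without the untreated column of table set 1 or without the INF-r library. The counts were 834 and 572 without JQ1 alone and 609 and 690 without I-BET alone, each with 1 residual degree of freedom. For APOL1 the interaction was 2.19 ± 0.24 (SE, adjusted p = 0.00142), for HLA-B -0.13 ± 0.17 (SE, adjusted p = 0.747) and for CD274 -0.40 ± 0.33 (SE, adjusted p = 0.586).

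JQ1 and I-BET were compared at the matched dose of 500 nM and the matched overnight time. Without INF-r, 51 genes were higher and 66 lower with JQ1 than with I-BET among 12788. Among them 3 of the 5 largest higher genes, such as PHOSPHO2-KLHL23, were readthrough genes. Some genes of the integrated stress response, which follows amino acid shortage, were higher with JQ1. DDIT4 was at 468 CPM with JQ1 and 104 with I-BET, CHAC1 at 58.3 and 12.6, ASNS at 929 and 284 and the serine synthesis gene PSAT1 at 304 and 105. In that list 6 of 17 were higher (median 0.53, percentile 100). The class I (0.11, percentile 98.8), interferon-gamma (0.20, percentile 99.99) and NF-kB (0.33, percentile 100) medians were slightly higher with JQ1, with 0, 0 and 2 genes past 2-fold, and the antiviral median did not stand apart (0.07, percentile 89.3). Higher medians also stood apart for S phase and mitosis (0.17), MYC and its targets (0.11), sterol synthesis (0.23) and stem-like markers (0.34), and lower ones for immediate early (-0.19), epidermal differentiation (-0.27) and mesenchymal genes (-0.10). The epidermal list no longer stood apart at a level filter of 5 CPM (-0.16), nor the mesenchymal list at a pseudocount of 0.1 (-0.099). ANKRD1 (13.8 and 41.9 CPM), CTGF (1252 and 2579 CPM), CYR61 (291 and 599 CPM) and the ERK phosphatase gene DUSP6 (135 and 338 CPM) were lower with JQ1. With INF-r, 100 genes were higher and 142 lower with JQ1 among 13083, led by near-identical or readthrough genes such as SMN1, SMN2 and NOMO3. The stress response list then had a median of -0.06, percentile 5.81, with ASNS at 186 CPM with JQ1 and 172 with I-BET. The class I (-0.18, percentile 0), interferon-gamma (-0.22, percentile 0) and NF-kB (-0.21, percentile 0.400) medians were then lower with JQ1, the reverse of their direction without INF-r, with 0, 0 and 0 genes past 2-fold. The antiviral (-0.31, percentile 0) and class II (-0.72, percentile 0.0700) medians were lower too, with 3 of 33 and 1 of 8 genes past 2-fold, and those of histone (0.26), glycolysis and hypoxia (0.15) and housekeeping genes (0.12) stood apart as higher. The antiviral genes OAS2 (16.4 and 37.7 CPM) and XAF1 (14.1 and 30.3 CPM) were lower with JQ1. The counts of genes past 2-fold followed the settings: at a level filter of 5 CPM they were 33 and 26 without and 30 and 35 with INF-r, and at a pseudocount of 0.1 174 and 210 without and 312 and 401 with it. In the count model with a compound term (edgeR, 2 residual degrees of freedom) 0 of 13220 genes differed at an adjusted p under 0.05, 235 had an unadjusted p under 0.05, and DESeq2 also gave 0. The spread in this fit includes changes with INF-r in the inhibitor effect and in the compound difference. Its common dispersion was 0.0254, against 0.00953 in the interaction fit. The count of 0 is therefore no sign that the compounds act alike. Leaving out 1 library gave at most 0 genes higher and 3 lower with JQ1. The JQ1 minus I-BET difference was 0.08 (95% interval -0.48 to 0.64) for HEXIM1, -0.08 (95% interval -0.41 to 0.26) for MYC, -0.10 (95% interval -0.39 to 0.18) for HLA-B and -0.29 (95% interval -0.84 to 0.25) for CD274, so differences within these intervals are not excluded.

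Across genes, the log2 differences of JQ1 and of I-BET against the shared untreated library had a Pearson correlation of 0.961 (Spearman 0.955, 12904 genes, which are not independent replicates). Unchanged libraries simulated against 1 shared control gave 0.497, and the covariance was 0.932 where the simulated covariance was 0.0479. Of the genes tested in both, 1230 were higher and 1460 lower with both compounds, where independent lists would share 173 and 244; the shared untreated library adds to this overlap. With the INF-r library shared, the correlation was 0.930, where simulation gave 0.520, and the covariance 0.682, where simulation gave 0.0687. With no library shared, JQ1 alone and I-BET with INF-r gave 0.750 (Spearman 0.739) and I-BET alone and JQ1 with INF-r 0.801 (Spearman 0.796). The same compound without and with INF-r gave 0.801 for JQ1 and 0.763 for I-BET. The JQ1 against I-BET differences themselves, without and with INF-r, had a correlation of 0.0701.

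**Figure D4:**
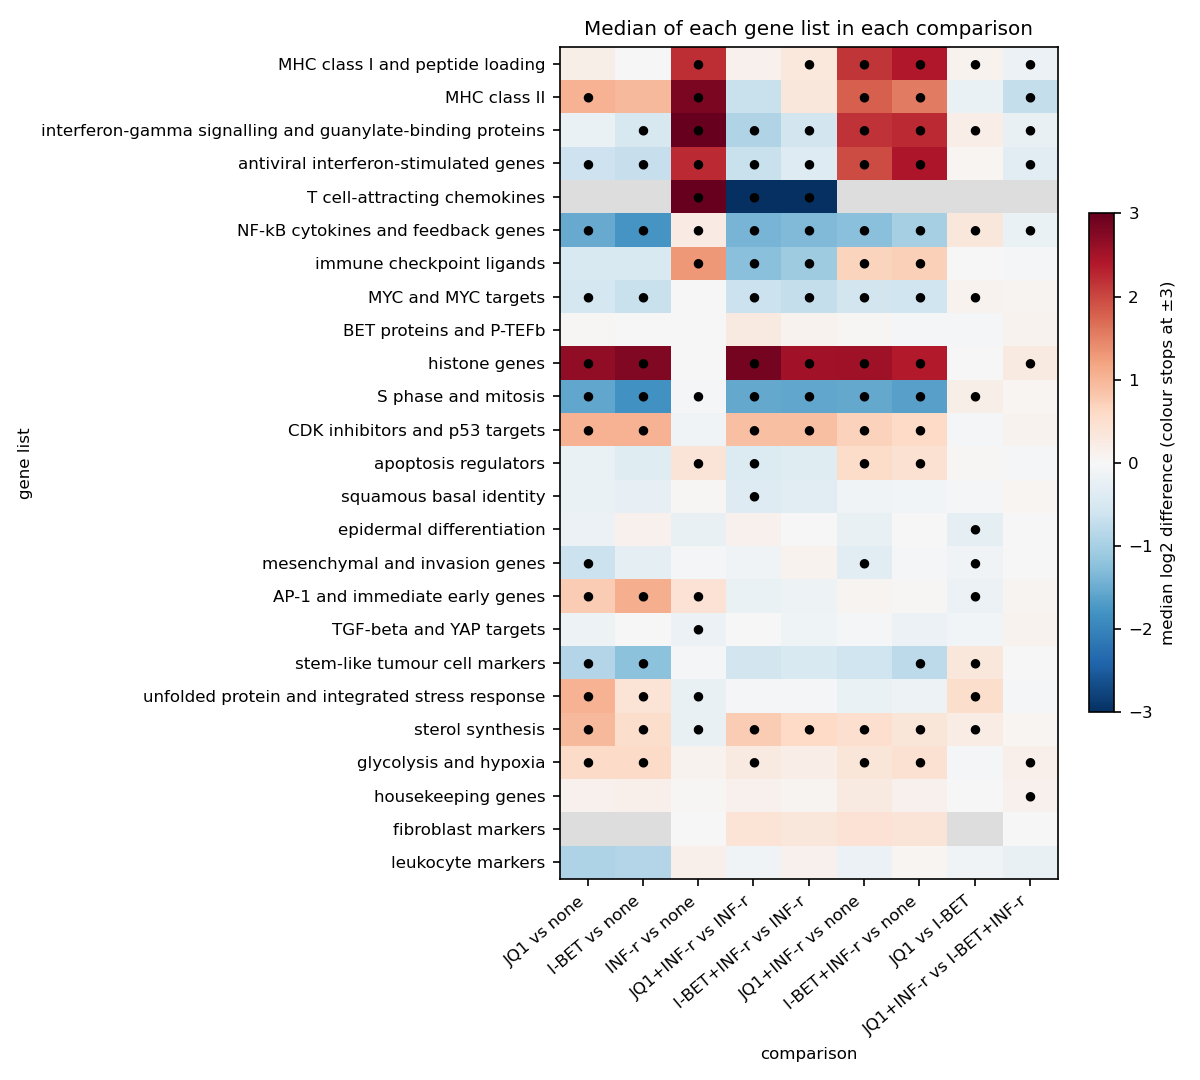
Median log2 difference of each gene list (down) in each comparison (across), red higher and blue lower, with a dot where the median lay at or above percentile 98 or at or below percentile 2 of 10000 random lists matched on mean expression; grey cells had fewer than 3 genes, and the endothelial list is left out for that reason. S phase and mitosis has medians of -1.56 and -1.82 with the inhibitors alone, and the class I list has a median of 2.21 with INF-r alone.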

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

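The interaction model and the tests of a weaker INF-r response and of a compound difference with INF-r were chosen after results were seen; the tests of chance in the INF-r library, of the untreated level and of reads split at random were set before theirs. Among 105 named genes that could be tested, the inhibitor effect differed between cells with and without INF-r at 37 (edgeR, adjusted p between 7.04e-04 and 0.0419). Over all 13220 genes tested, 362 had a more positive and 238 a more negative effect. Named genes were chosen partly for large differences in these same libraries, which raises their share. None of the 37 changed direction without JQ1, I-BET, JQ1 with INF-r or I-BET with INF-r. The untreated column of table set 2 does not enter this term, so leaving it out is no check. The untreated column of table set 1 and the INF-r library, on which every value rests, could not be left out. The inhibitor effect was more positive with INF-r, by the log2 difference given, for TGFB2 (4.19), APOL3 (3.41), KRT80 (2.88), BMI1 (2.43), APOL6 (2.41), APOL1 (2.19), TP63 (2.08), CDT1 (1.77), PDPN (1.77), PSMB10 (1.63), WARS (1.49), UHRF1 (1.49), GBP3 (1.48), MCM5 (1.45), ERAP2 (1.31), EPSTI1 (1.25), PSMB8 (1.07) and ZMYND8 (1.05). It was more negative for CTGF (-3.29), SOCS1 (-3.17), KLF4 (-3.15), MMP3 (-2.96), CTSS (-2.84), SOD2 (-2.34), CDKN1A (-1.94), ATF3 (-1.89), SLC6A8 (-1.81), FOSL1 (-1.80), TGFB1 (-1.74), NDRG1 (-1.59), GADD45B (-1.57), KRT17 (-1.30), NOTCH1 (-1.29), INSIG1 (-1.28), IRF7 (-1.20), IFI30 (-1.06) and TNC (-0.97). SOCS1, CTSS, APOL3 and TGFB2 had 3 or fewer reads in at least 1 library, so the size of their values depends on the prior count. The untreated columns of the table sets differed at least 2-fold for SOCS1, CTSS, TGFB2, MMP3 and CDKN1A. Only that of table set 1 enters their values here. Each value rests on 1 library per condition, and the libraries with INF-r are in table set 2 alone. The p-values measure only how far JQ1 and I-BET differ, since the untreated columns and the INF-r library are fitted exactly.

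Among 305 genes higher with INF-r alone at 5 CPM or more, 99 were at least 2-fold lower with both inhibitors added and 20 at least 2-fold higher. Over 12987 genes past the level filter of 1 CPM, 1008 were lower and 988 higher with both. The share that was higher is thus not above that over all genes. The share that was lower is above it, but choosing genes as high in the INF-r library adds to it. A weaker INF-r response in the combination libraries would lower the effect throughout. The INF-r effect was smaller by 1 on the log2 scale in both inhibitor backgrounds at 76 of them and larger by 1 in both at 29, which is 9.51% (95% Wilson interval 6.70 to 13.3) against 3.0% of 11255 other genes. The relative effect was thus not smaller throughout. However, an inhibitor that lowers a gene without INF-r also makes this relative effect larger. Both backgrounds also share the INF-r library and the untreated column of table set 1, so they are not separate checks. These values therefore cannot decide on a weaker response, which stays open. The inhibitor effects without and with INF-r share no library. Their correlation was 0.589 (bootstrap interval 0.483 to 0.676) across the 274 of these genes at 1 CPM or more in a library of table set 1. That argues against chance in the 1 INF-r library as the whole cause at those genes. It cannot exclude a part played by chance, because the genes were chosen as high in the library they are then compared with. A candidate explanation is that the inhibitors reduce most the genes that are nearly silent without INF-r: the untreated level and the inhibitor effect had a Spearman correlation of 0.255 (interval 0.142 to 0.364), positive but not clear of the 0.3 set beforehand. It remains open, as does a difference between the table sets in counting, preparation or culture.

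The genes at which JQ1 and I-BET differed without INF-r were weighed too. The 219 genes called in a random part of the reads had a median difference of 0.722 the same way in the remaining reads (interval 0.614 to 0.816), where 72 passed 2-fold. That argues against counting error of independent reads. Copies of 1 molecule can fall in both parts, so error from the sampling of molecules is not excluded. A compound difference that also holds with INF-r would keep its direction. Of 97 genes called without INF-r, 51, or 52.6% (Wilson interval 42.7 to 62.2), differed the same way with it. A compound effect that INF-r removes and a difference between single cultures both stay open, and no replicate separates them.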

How the results depend on the processing

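No paired analysis was possible because each condition has 1 sample and the labels give no replicate numbers. The count models, the splits of the samples, the untreated column of the other table set and the settings of the correlations were chosen after the data were seen; the other settings were planned. Leaving out the level filter could not change the counts, since with a pseudocount of 1 a gene under 1 CPM cannot pass 2-fold, so it tests nothing there. Median-centring left every count within 1.5 times, and no named gene past 2-fold and no list median that stood apart changed sign under the pseudocount of 0.1, the level filter of 5 CPM or centring. A list median that did not stand apart could turn, and that of class II for I-BET with INF-r against INF-r went from 0.34 to -0.96 and stood apart at a level filter of 5 CPM. With the untreated column of the other set, 498 genes were higher with INF-r, of which 292 were among the 468, and every count stayed within 1.5 times. The authors' deposited calls were fewer: 450 higher and 539 lower for JQ1, 618 and 678 for I-BET, 126 and 12 for INF-r, 276 and 205 for JQ1 with INF-r, and 274 and 163 for I-BET with INF-r; they use an FDR under 0.05 without the 2-fold rule or the level filter, and the cause of the difference was not tested. A level filter of 5 CPM, which leaves fewer genes, gave 307 and 127 for INF-r, 33 and 26 for JQ1 against I-BET, 30 and 35 for the same with INF-r, and 20 genes lower with INF-r in the 3 backgrounds. A pseudocount of 0.1, which lets low counts pass, gave 587 lower for INF-r, 174 and 210 for JQ1 against I-BET, 312 and 401 with INF-r, and 386 higher and 167 lower in the 3 backgrounds. DESeq2 gave 193 and 16 genes for INF-r and 140 with a more positive inhibitor effect with INF-r; the cause was not tested. Leaving out 1 library gave 2395 to 3403 genes that rose and 2657 to 3836 that fell with an inhibitor, and 44 to 491 and 1 to 225 with INF-r; the highest INF-r counts were without the INF-r library and the lowest without JQ1 with INF-r, they were 298 and 60 without the untreated column of table set 1, and the term could not be fitted without the untreated column of table set 2. The inhibitor effect was more positive with INF-r at 278 to 834 and more negative at 183 to 690 genes with 1 library left out; the counts were 834 and 572 without JQ1 and 609 and 690 without I-BET, and the term could not be fitted without the untreated column of table set 1 or the INF-r library. For JQ1 against I-BET they were 0 to 0 and 0 to 3, the most lower without I-BET or INF-r. Of 636 list medians under alternatives, 18 changed whether they stood apart, and of 2473 values of named genes, 38 crossed 2-fold or changed direction. Of these, 27 lost and 3 gained the 2-fold call with the untreated column of the other set, and 3 changed direction with it: CSF3 (-1.44) and CDKN1A (-0.41) with INF-r and IVL (0.0186) with I-BET. Of 160 other values of the INF-r effect by inhibitor, 149 moved by under 0.5 on the log2 scale or 1.5 times; the endothelial list had no value there at a level filter of 5 CPM. Splits of the 6 samples, with both untreated columns kept on 1 side, were too few for a share under 0.05. For the inhibitor term there were 15 splits into 4 and 2 (real 6934 genes, highest other 0), and for INF-r 10 into 3 and 3 (real 115, highest other 11). Table set 2 has the lower depth, so a gene at 0 reads in its untreated column is known only to within 0.608 CPM.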

Other observations

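The comparison of the 2 untreated columns and its test of counting error were chosen after the result was seen; the test of antisense pairs was set before its result.  SOCS1, a feedback inhibitor of cytokine signalling, was at 3.0, 30.1 and 23.9 CPM untreated, with JQ1 and with I-BET, and NLRC5 at 16.2, 35.4 and 22.5 CPM, which passed 2-fold with JQ1 (1.09, or 0.88 against the other untreated column) and not with I-BET (0.45). The interferon-induced gene IFI6 was at 8.63, 30.8 and 31.1 CPM, whereas IFIT3 (13.1, 4.53 and 2.82 CPM), GBP3 (44.4, 7.25 and 6.06 CPM), EPSTI1 (22.9, 3.44 and 2.73 CPM) and APOL3 (6.29, 0.181 and 0.341 CPM) were lower. With INF-r present, TRIM22 was at 126, 21.5 and 39.4 CPM, XAF1 at 76, 14.1 and 30.3 CPM and BST2 at 20.6, 3.61 and 6.74 CPM with INF-r, JQ1 with INF-r and I-BET with INF-r. The macrophage-associated gene CD68, also expressed in other cells, was at 14, 35 and 51.8 CPM with the inhibitors alone and was the 1 leukocyte marker at 5 CPM or more past 2-fold there. Of 14 leukocyte, 10 fibroblast and 10 endothelial markers, 3, 1 and 1 were past the level filter in the comparison of JQ1 with untreated, with leukocyte medians of -0.93, percentile 9.23 for JQ1, -0.87, percentile 10.8 for I-BET and 0.14, percentile 72.7 for INF-r, and a fibroblast median of 0.01, percentile 60.6 for INF-r. For INF-r against untreated, in table set 2, the counts past the filter were 3, 4 and 1. The collagen gene COL1A2 was at 0.146 CPM in the untreated column of table set 1 and at 20.1 CPM in that of table set 2.

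The untreated columns of the 2 table sets carry 1 label but differed. Counting error of independent reads would give a chi-square per degree of freedom near 1, and 9.40 was found, so it is argued against. Antisense-named genes were at least 2-fold higher in table set 2 at 35 of 235 (14.9%), against 1.52% of the other genes, and by raw library size they summed to 2000.1, 2021 and 1946 CPM in the untreated, JQ1 and I-BET libraries of table set 1 and to 3027, 2871, 2970.5 and 3072 CPM in the untreated, INF-r, JQ1 with INF-r and I-BET with INF-r libraries of table set 2. If reads of the sense partner were counted there more in table set 2, antisense genes would follow their partners more closely in that set; the Spearman correlation of their inhibitor effects was 0.270 in table set 1 and 0.291 in table set 2 over 206 pairs, a difference of 0.0206 (bootstrap interval -0.0857 to 0.127). That interval leaves the explanation open; since the antisense sums differ between whole table sets, a difference in annotation or preparation between the sets may be their cause, the other genes may also reflect the culture, and no biological explanation was tested.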
